A study of Homo sapiens with 41 samples.

How the data were processed

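Chromatin immunoprecipitation sequencing of CTCF, RAD21 and Pol II from T47D cells was deposited as 29 peak lists, each from a single library, out of 41 samples. The other 12 samples, inputs, carry no peak list. The submitters' processing notes name cutadapt, Bowtie2 version 2.2.6, MACS2 and the build hg38, and for set 1 also DiffBind version 2.4.6, DESeq2 and HOMER. The lists have the layout that MACS2 writes. The roles of these tools, the calling threshold and the control used are not given in the sources used here. CTCF and RAD21 lists are narrow peaks with summits and Pol II lists are broad regions.

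The authors' lists give for each peak a fold enrichment, which is a ratio to the caller's background, together with deposited -log10 p and -log10 q values and a deposited integer score. These belong to each peak and were used only to rank, filter or describe peaks within a list. In the Pol II lists the deposited -log10 p hardly followed the width of the regions (rank correlation -0.035 to 0.021), and recurrence in the replicate rose little with it (from 34.0 to 37.1% and 48.5 to 50.3% untreated, and 26.0 to 33.2% and 16.8 to 21.8% at 1 h, lowest to highest quintile), so rankings and filters by score carry little information there, including the rank in the rule for naming Pol II genes. A deposited -log10 q under 1.3 was found in 50.0 and 48.5% of untreated and 80.05 and 92.4% of 1 h Pol II regions. Several other Pol II settings were explored before this was found, and a flank comparison that had been oriented by those scores was dropped.

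Samples were grouped by title. Titles and tags disagree in places. The pre-treatment tag contradicts the title on triptolide in 6 of the 12 libraries of set 2, the 30 min CTCF library and the Pol II replicate 2 libraries carry another replicate number in the tag than in the title. The series text and the titles give slightly different NaCl concentrations, of which that of the titles (110 mM) was used. Replicates 1 and 2 are numbered in the titles, and replicate 3 is the library of set 2. No lists were identical (0 pairs). For CTCF, libraries with the same number or set deviated together from their group means (r = 0.13, 0.38 and 0.34 across sites), a pairing that rests on the numbers in the titles and on the shared submission, and for no comparison did it replace the unpaired design.

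Lists were read on chromosomes 1 to 22 and X and compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak counted as kept when a peak of the other list overlapped it by 1 bp. Overlapping peaks of all libraries compared were merged into sites, and a site was lost when present in all untreated and in no 1 h library, gained in the opposite case and kept when present in every library. Peak numbers were compared as log2 values by exact 2-sided permutation tests, which reach p = 0.1 with 3 libraries against 3 and 0.333 with 2 against 2. Lost and gained counts were set beside those of other splits of the same libraries (10 for 3 against 3, and 3 for 2 against 2). Odds ratios of being kept were tested with Fisher's exact test across peaks within each replicate, and within quintiles of fold enrichment with the Mantel-Haenszel estimate and test. Gene lists were tested with Fisher's exact test and Benjamini-Hochberg adjustment over 19 lists at 0.05. Shares of single libraries have exact Clopper-Pearson 95% intervals, which cover counting error alone.

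Genes came from a RefSeq table of GRCh38.p14 with 19970 protein-coding genes on these chromosomes. It gives gene spans without strand, so the planned comparison at transcription starts became a peak within 1 kb of either gene end, the planned downstream flank became the 10 kb past both ends of genes without another gene there, and the gene body was taken without 1 kb at each end in genes over 3 kb. A planned comparison by CTCF motif needs the genome sequence and was not run. All members of the gene lists were found in the table except 2 of the 19 imprinted genes.

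The depth of each library was estimated from its list as the caller's background, recovered from fold enrichment and -log10 p of up to 1500 peaks with -log10 p under 200. It ranged from 1.79 to 3.87 for CTCF and from 0.535 to 2.29 for RAD21 in pileup units. It cannot be had for the broad Pol II lists. The estimate explained 7.40 to 45.1% of the sampled peaks within a tolerance of 0.005, those whose background was the most common value.

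Named genes follow a rule. For CTCF and RAD21 these are up to 10 lost, kept and gained sites within 1 kb of a gene end with the highest percentile of fold enrichment in the library where they ranked lowest. For Pol II they are the 10 lost and gained genes with the highest such percentile of -log10 p, the 10 with the largest rise and fall of body coverage and the 10 with the largest rise of flank coverage, and members of the gene lists. The lists included genes of the osmolyte and NFAT5 pathway, the immediate early and MAP kinase response, heat shock and chaperones, the integrated stress response, cytosolic ribosomal proteins, glycolysis and housekeeping, replication-dependent histones, luminal breast identity, oestrogen and progesterone targets, the cell cycle, cohesin and loop factors, transcription elongation and termination, haematopoietic, neuronal and muscle, and fibroblast markers, HOX clusters, clustered protocadherins and imprinted genes, and 1 more that is not used here.

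The gene lists, the rule for naming genes, the comparison over other splits and the alternatives listed next were fixed before the data were examined. The alternatives were -log10 q of at least 5, fold enrichment of at least 5 (narrow) or 3 (broad), equal numbers of peaks by -log10 p, reciprocal overlap of 50%, summits within 100 bp, all contigs, each library left out, pairs of the same number, set 1 alone, fold enrichment quintiles, equal covered length, a region over the gene end itself, 5 kb flanks and genes over 20 kb. Regions of at least 2 kb and equal covered length by width were added for Pol II after seeing the data. The merging, overlap, coverage and background steps were tested on simulated data. With 20200 sites, 1000 of them lost and 200 gained, and 10% of sites missed per library, the 3 against 3 comparison found 749 lost (743 calculated from the simulated settings) and 164 gained sites (160 calculated).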

Results

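T47D, an established human breast carcinoma line of luminal type, was kept without steroid hormones and serum and then exposed to 110 mM NaCl, which raises the osmolarity of the medium. Chromatin immunoprecipitation with sequencing was used to map CTCF (the insulator protein that stops loop extrusion), RAD21 (a subunit of the cohesin ring) and RNA polymerase II (Pol II). The peak lists comprised 13 CTCF, 12 RAD21 and 4 Pol II lists, each called on a single library. CTCF had 3 libraries without stress, 2 at 7.5 min, 1 at 30 min and 3 at 1 h of NaCl. RAD21 had 3 libraries without stress, 3 at 1 h and 3 at 1 h followed by 1 h back in isotonic medium, and Pol II had 2 without stress and 2 at 1 h. A separate submission, called set 2 here, contributed replicate 3 of these groups, a CTCF recovery library and 6 libraries pre-treated with 500 nM triptolide, an inhibitor of transcription initiation. Read totals are not in the lists, so the number of called peaks is given per library. It ranged from 20678 to 59843 for CTCF, from 3344 to 40969 for RAD21 and from 88046 to 216968 for Pol II on chromosomes 1 to 22 and X. Nothing in the labels states that replicates were separate cultures, so permutation p-values measure the spread between these libraries, which may be technical. Tests across peaks or genes measure no spread between libraries. All coordinates are hg38.

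CTCF was called at fewer places after 1 h of NaCl, and the places that dropped out were mostly those with low enrichment. Untreated libraries had 47416 ± 11079 peaks (SD, n = 3) and 1 h libraries 30532 ± 7397 (SD, n = 3), a log2 ratio of -0.64. In replicate 1 the peaks kept at 1 h were 7.64% of the lowest quintile of fold enrichment and 99.1% of the highest, in replicate 2 they were 43.6% and 99.2%, and in replicate 3 24.5% and 95.1%. Weak peaks also recurred less between untreated libraries. In the lowest quintile of -log10 p 17.4% (replicate 1 in 2), 87.8% (2 in 1) and 39.6% (3 in 1) recurred, and in the highest at least 99.9%. Sites present in every untreated and every 1 h library numbered 14606, and those near gene ends included the site at APOB, which encodes the main apolipoprotein of low-density lipoprotein (chromosome 2, 21042728 to 21043306), at CTCFL, the testis paralogue of CTCF (chromosome 20, 57495074 to 57495840). Others were at LMO2 (chromosome 11, 33857612 to 33858342) and at FGF1, a fibroblast growth factor (chromosome 5, 142698927 to 142699741). ERMN, RFX7, AKR1A1, STYK1 and LOC124900192 were also among the kept sites near gene ends with the highest enrichment rank. A 2-sided exact permutation test of log2 peak number gave p = 0.1, the smallest that 3 libraries against 3 allow, and the log2 ratio was -0.56 within set 1 and -0.81 within set 2.

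Sites lost by CTCF, present in all 3 untreated and in no 1 h library, numbered 1498, against 28 gained. Of the lost sites 9.08% lay within 1 kb of a gene end, compared with 16.9% of the kept ones. The lost sites with the highest rank stood at TSR2, a ribosome maturation factor (chromosome X, 54447364 to 54447844), at HVCN1, a voltage-gated proton channel (chromosome 12, 110704659 to 110705134), at BBS10, a Bardet-Biedl syndrome chaperonin-like gene (chromosome 12, 76347037 to 76347511), and at NEIL2, a DNA glycosylase (chromosome 8, 11787788 to 11788216). They also stood at RAET1G, ZNF774, OR6J1, SSBP4, MORC4 and KLF13, all at or below the 51.7 percentile of enrichment in the library where they ranked lowest. The gained site near a gene end was at ZNF335 (chromosome 20, 45971700 to 45972221), at the 0.39 percentile. Across all pairs of libraries 55.3% of untreated peaks were overlapped at 1 h (28.9 to 72.7%), against 71.4% between untreated libraries (52.97 to 97.5%), so the ranges overlapped. The lost count depended on single libraries. Without untreated replicate 3 it was 9689, without untreated replicate 2 it was 4293 and without 1 h replicate 1 it was 2594, and within set 1 it was 9702, with 33 to 155 gained over the libraries left out. With the 22018 strongest peaks of each library, 74.3% were kept, 693 sites were lost and 175 gained.

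Of the 25596 CTCF sites that all untreated libraries shared, 57.1% were kept in every 1 h library and 5.85% were lost from all of them. Of the sites near genes of the immediate early and MAP kinase response that all untreated libraries shared, 8 of 10 were kept in every 1 h library, and the site at MYC, the growth-promoting transcription factor, was lost. Cohesin, CTCF and loop factor genes kept 9 of 10, clustered protocadherins 8 of 12, cytosolic ribosomal protein genes 8 of 11, HOX clusters 5 of 7, glycolysis and housekeeping genes 6 of 7 and luminal breast identity genes 5 of 5. Transcription elongation and termination genes kept 4 of 6 and lost the site at CDK9, the kinase of the elongation factor P-TEFb, while haematopoietic markers kept 2 of 3 and lost that at ITGAM, an integrin of myeloid cells. The integrated stress response kept 3 of 3, heat shock genes 2 of 3, the osmolyte and NFAT5 pathway 2 of 2, fibroblast markers 2 of 2, imprinted genes 2 of 3, and oestrogen targets and cell cycle genes 1 of 2 each. Replication-dependent histones kept 0 of 4 and neuronal and muscle markers 0 of 2, without a site called lost in either. These counts were not tested. Within 1 kb of gene ends over the whole genome, 136 CTCF sites were lost and 2470 kept.

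**Figure D1:**
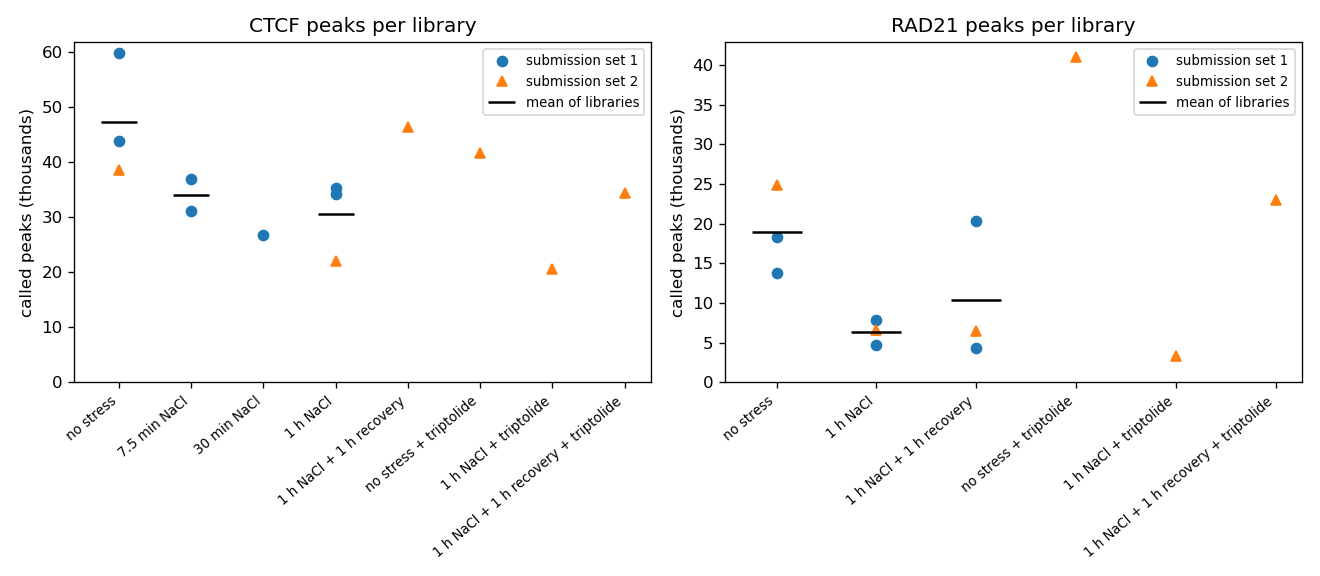
Called CTCF peaks (left) and RAD21 peaks (right) per library in units of 1000, by condition, with circles for set 1, triangles for set 2 and bars for the mean of groups with several libraries. The 3 RAD21 libraries at 1 h lie between 4761 and 7843 peaks, below the untreated libraries at 13762 to 24931, and the 3 recovery libraries lie at 4397, 6492 and 20400.

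**Figure D2:**
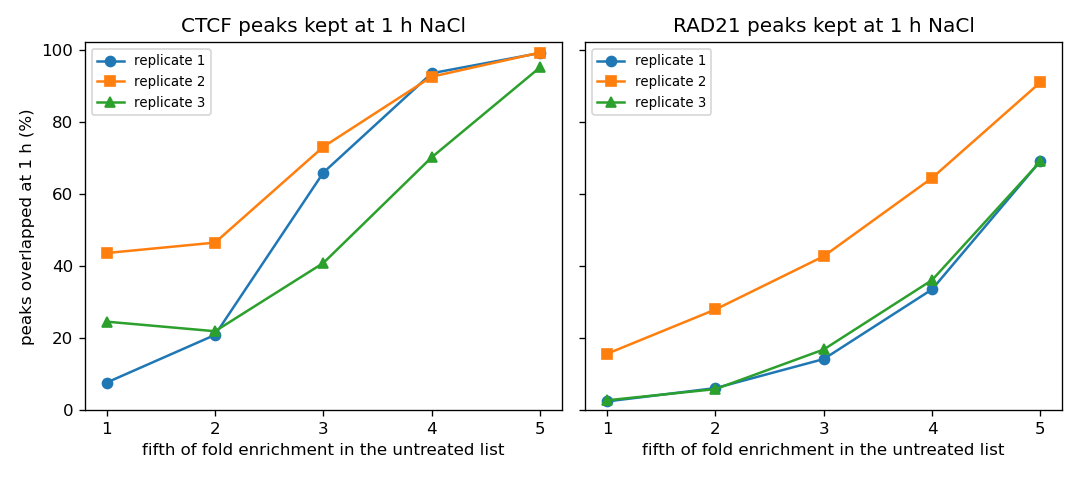
Share of untreated CTCF peaks (left) and RAD21 peaks (right) overlapped by a peak of the matched 1 h library, by quintile of fold enrichment in the untreated list, with a line per replicate. The kept share of RAD21 goes from 2.404 to 69.1% in replicate 1, from 15.6 to 90.9% in replicate 2 and from 2.71 to 69.0% in replicate 3.

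The course of CTCF binding during stress was sampled at 7.5 and 30 min. CTCF lists were already shorter at 7.5 min, with 34018 ± 4163 peaks (SD, n = 2) against 59843 and 43835 in the untreated libraries of the same set, and the 30 min library had 26737. Within set 1, 63.0% of untreated peaks were overlapped at 7.5 min, 51.4% at 30 min and 63.3% at 1 h. The log2 ratio of peak number at 7.5 min was -0.60 with an exact permutation p = 0.333, the smallest that 2 libraries against 2 allow (2-sided), and ran from -0.82 to -0.37, the latter without untreated replicate 1. The 30 min value has no replicate.

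RAD21 was called at fewer places after 1 h of NaCl. Of the 10098 sites that all untreated libraries shared, 34.5% were kept in every 1 h library and 32.4% were lost from all of them. The size of this fall was not tested against that of CTCF. Untreated libraries had 18997 ± 5617 peaks (SD, n = 3) and 1 h libraries 6411 ± 1553 (SD, n = 3), a log2 ratio of -1.55. Of the 13 RAD21 sites shared by all untreated libraries near genes of the immediate early and MAP kinase response, 0 were kept in all 1 h libraries and 8 were lost in all of them, at DUSP1, DUSP4 and DUSP6 (phosphatases of MAP kinases), KLF4 and KLF10 (zinc finger transcription factors) and IER5. Luminal breast identity genes had 8 shared sites, of which 0 were kept in all and 4 were lost, at CDH1 (E-cadherin), ELF3, TFAP2C and TRPS1. Lost sites also stood at CCND1 and SIAH2 among 3 sites of oestrogen and progesterone targets, at RPL13, RPL4 and RPS19 among 3 of ribosomal protein genes, at GNAS, GRB10 and PEG10 among 4 of imprinted genes. Others were at SLC6A6, the taurine transporter, among 5 of the osmolyte and NFAT5 pathway, at DDIT4 among 3 of the integrated stress response, at CTCF itself among 7 of cohesin and loop factors, at PCDHB2 among 3 of protocadherins, and at PKM and PCNA. Sites of haematopoietic markers were kept in 2 of 2 cases and of fibroblast markers in 1 of 1, HOX clusters kept 2 of 4 and elongation genes 1 of 3. Heat shock genes, replication-dependent histones and neuronal and muscle markers had 0 shared sites. These list counts were not tested. Within 1 kb of gene ends over the whole genome, 703 RAD21 sites were lost and 364 kept.

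Over the genome 3271 RAD21 sites were lost, 2 gained and 3482 kept, and 21.5% of the lost sites lay within 1 kb of a gene end against 10.5% of the kept ones. The lost sites with the highest enrichment rank were at RAMP1, a receptor activity-modifying protein (chromosome 2, 237858281 to 237858762), RPS26, a ribosomal protein gene (chromosome 12, 56041420 to 56041905), PKM, pyruvate kinase (chromosome 15, 72199640 to 72200130), SDC1, the proteoglycan syndecan 1 (chromosome 2, 20225210 to 20225737), ADORA2B, an adenosine receptor (chromosome 17, 15849013 to 15849500), HTR3D, CD300LG, SPMIP6 and SNRPE. Kept sites with the highest rank were at DHX8, an RNA helicase of splicing (chromosome 17, 43483433 to 43484223), STAT6, the interleukin 4 signal transducer (chromosome 12, 57112226 to 57112753), FGF1, THPO, EBF1, GRM4, NRSN2, CYB5R2, RTP2 and COPZ2. The 2 gained sites were at RBM45 and SPECC1. Of untreated peaks 31.7% were overlapped at 1 h (18.9 to 48.3% over pairs), against 69.0% between untreated libraries (42.5 to 87.0%). The exact 2-sided permutation p of the peak number was 0.1, the smallest that 3 libraries against 3 allow, with log2 ratios of -1.38 in set 1 and -1.91 in set 2. Without untreated replicate 2 the lost count was 7630, without untreated replicate 3 there were 17 gained sites, and with the 4761 strongest peaks of each library 62.9% were kept, 357 sites were lost and 229 gained.

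Whether cohesin returns once cells are back in isotonic medium was asked with the recovery libraries. Recovery lists differed in length, with 4397, 20400 and 6492 RAD21 peaks in replicates 1 to 3, and so did the share regained. Of the peaks present untreated and absent at 1 h within the same replicate, replicate 2 regained 81.4%, replicate 1 12.5% and replicate 3, of set 2, 11.4%, while other 1 h libraries held 6.85%, 18.7% and 6.64% of them. The mean was 35.1 ± 40.1% (SD, n = 3). With the same number of strongest peaks in the 3 lists of a replicate (4397, 7843 and 6492), the shares regained were 61.9%, 60.8% and 59.4%. Other 1 h libraries at that number held 27.6%, 8.30% and 19.6% of these peaks, and other untreated libraries 62.7%, 49.2% and 59.1%. The mean share regained was then 60.7 ± 1.24% (SD, n = 3). This cut shortened the recovery list of replicate 2 from 20400 to 7843 peaks and left those of replicates 1 and 3 at full length. The untreated lists were shortened in every replicate. The peaks counted as lost fell from 13716, 7115 and 18431 to 1750, 2535 and 1974, all among the strongest untreated peaks. CTCF, with a recovery library in set 2 alone, regained 87.4% of its lost peaks (95% exact binomial interval 86.9 to 87.9%, covering counting error alone). The other 1 h CTCF libraries held 47.5% of those, but they are of set 1, while the untreated and recovery lists compared are of set 2. With equal peak numbers CTCF regained 78.6% (77.5 to 79.6%), and the same 1 h libraries of set 1 held 36.7%. RAD21 peak number in recovery over 1 h had a log2 ratio of 0.41 with an exact permutation p = 0.9 (2-sided, smallest possible 0.1), 0.63 within set 1 and -0.030 within set 2. Without recovery replicate 2 the ratio was -0.23 and the mean regained share 11.985%. The set 2 recovery libraries of RAD21 and CTCF were assigned by their titles, and the tag of each names triptolide.

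RAD21 peaks that remained under stress were mostly those at CTCF sites. In the untreated libraries 93.8%, 88.2% and 76.9% of RAD21 peaks overlapped a CTCF peak of the same condition and set, and at 1 h 99.1%, 91.4% and 90.9% did. The CTCF peaks were pooled from 2 libraries per condition in set 1 and came from 1 in set 2, so replicate 3 had a smaller reference. The means differed by 7.51 percentage points (exact permutation p = 0.3, 2-sided, smallest possible 0.1), and by 2.79 without untreated replicate 3 and 11.3 without untreated replicate 1. RAD21 peaks at CTCF were kept at 26.6%, 52.8% and 33.4% in replicates 1 to 3 and those away from CTCF at 1.95%, 14.9% and 1.72%. RAD21 peaks near gene ends were kept less often than others, at 13.7% against 27.4%, 34.9% against 53.4% and 21.7% against 26.6%, but within quintiles of fold enrichment the log2 odds ratios were -0.67, 0.025 and 0.80. CTCF peaks bound by RAD21 were kept at 88.3%, 90.0% and 63.7% and other CTCF peaks at 43.6%, 59.5% and 37.4%, with log2 odds ratios of 3.28, 2.62 and 1.55. Within quintiles these were 1.35, 2.31 and 0.32. Fisher's exact test across peaks gave a p below what could be written, shown as 1e-300, in every replicate for RAD21-bound CTCF peaks, and peaks are not replicates of the treatment. CTCF peaks near gene ends had log2 odds ratios of 0.35, 0.91 and 0.15 against distal ones (largest Fisher's exact p = 3.01e-05), a call that ended with -log10 q of at least 5 (largest p = 0.648), with fold enrichment of at least 5 (0.34) and within quintiles, where the ratios were 1.57, 2.12 and -0.019 (0.672).

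Triptolide was applied before stress to ask how the binding of both proteins depends on transcription, with 1 library per condition and therefore no test. CTCF lists with triptolide held 1.08 times as many peaks as those without in unstressed cells, 0.939 times at 1 h of NaCl and 0.744 times in recovery. RAD21 lists held 1.64 times as many in unstressed cells (40969 against 24931), 0.504 times at 1 h (3344 against 6630) and 3.54 times in recovery (22967 against 6492). Set against each of the 3 RAD21 libraries without triptolide of a state, from both sets, the ratio ran from 1.64 to 2.98 in unstressed cells, 0.426 to 0.702 at 1 h and 1.13 to 5.22 in recovery. For CTCF it ran from 0.697 to 1.08 in unstressed cells and 0.585 to 0.939 at 1 h. Of the RAD21 peaks in triptolide-treated unstressed cells 17375 were absent from the untreated library of set 2, and 28.4% of these lay near gene ends, compared with 10.5% of that library's peaks and 17.4 and 27.4% in untreated replicates 1 and 2, while 43.9% overlapped an untreated CTCF peak. In recovery 77.9% of the untreated RAD21 peaks (95% exact binomial interval 77.4 to 78.4%) were present in the library titled with triptolide and 25.7% (25.2 to 26.2%) in the library titled without, while recovery replicates 1 and 2 of set 1 held 17.4 and 63.7% of the same peaks. The pre-treatment tag contradicts the title on triptolide in 6 of the 12 libraries of set 2, and titles were followed. By the tags both libraries of each condition had the same pre-treatment, and no comparison with and without triptolide would remain.

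Pol II regions were called at fewer gene ends and over less of the gene bodies after 1 h of NaCl, in lists that also differed in make-up. The lists covered 291.9 and 257.2 Mb untreated and 212.3 and 261.7 Mb at 1 h. Of the covered bases 72.1 and 71.3% lay in protein-coding genes untreated and 55.1 and 50.9% at 1 h. A larger part of the coverage thus lay outside these genes at 1 h. The untreated lists held 105302 and 88046 regions, of which 50.0 and 48.5% had a deposited -log10 q under 1.3, and the 1 h lists held 107396 and 216968, of which 80.05 and 92.4% did. Untreated libraries had a region within 1 kb of either end of 12612 and 13473 protein-coding genes and 1 h libraries of 8722 and 11059, out of 19970. Genes that lost their end regions in both 1 h libraries numbered 2134, including PSMD13, a proteasome subunit, PARG, which removes poly(ADP-ribose), SPAG1, CGRRF1, ZCCHC17, ARHGEF4, MINDY4, SLC35G3, CLDN25 and TPTEP2-CSNK1E. Genes that gained them numbered 625, including IL2RA, the interleukin 2 receptor alpha chain, MYL2, a myosin light chain of heart muscle, ATCAY and the adjacent ZFR2, PRR35, TMEM151B, OPN5, CCDC63, GREP1 and FAM171A1. ATCAY (chromosome 19, 3880685 to 3928082) was covered over 1.71 and 1.81% of its length untreated and 100.0% in both 1 h libraries, and PSMD13 (chromosome 11, 236976 to 252984) over 32.6 and 22.8% untreated and 0.0% at 1 h. The other splits of the 4 libraries gave 228 and 667, and 465 and 348 genes, and 3 splits are too few for a share under 0.05. Counts rose when a library was left out, to 3751 lost without 1 h replicate 1, 4981 without 1 h replicate 2, and 985 to 1629 gained over the 4 libraries left out in turn.

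Among 4208 genes over 3 kb with an end region in all 4 libraries, the covered share of the body was 48.7 and 44.0% untreated and 35.1 and 29.7% at 1 h. Both untreated libraries exceeded both 1 h libraries in 1910 of these genes (45.4%) and the reverse held in 820 (19.5%). Exchangeable libraries without tied shares would give 16.7% in a direction. Tied shares occurred, the lists differed in make-up and neighbouring genes are not independent, so neither share was tested against that value. Full coverage untreated and none at 1 h was seen in DMAP1, a subunit of chromatin remodelling complexes, ATP5MC3, a subunit of ATP synthase, RABGGTB, TMEM69, PRADC1, CYB561D2, TSPYL4, KLHDC7A, CFAP276 and C2orf72. The opposite was seen in NFKBIE, an inhibitor of NF-kappa B, IFI30, RAB3A and GARIN5B, with at most 5.14% untreated and at least 94.7% at 1 h also in EFNA2, RPUSD1, ZSCAN10, HGFAC, KIF21B and TRPM5. Flanks of 10 kb past both ends of 406 genes without close neighbours were covered over 32.8 and 30.5% untreated and 27.0 and 24.4% at 1 h, yet coverage was higher at 1 h around KCNJ5, PARS2, WIPI2, FAM124A, PTPRS, PECAM1, EIF1, SLC41A1 and DMBX1, all among the 10 with the largest rise. EIF1, a translation initiation factor, was covered over its whole length in all 4 libraries and its flanks over 31.8 and 39.7% untreated and 83.1 and 80.5% at 1 h. The exact permutation p was 0.333 for the gene number, the body and the flanks alike (2-sided, n = 2 per group), the smallest possible.

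The Pol II values depended on which regions were counted, and their deposited scores were of little use for choosing them. In the 4 Pol II lists the rank correlation of -log10 p with the region's own width lay between -0.035 and 0.021, against 0.67 to 0.90 in the 25 CTCF and RAD21 lists. With regions of at least 2 kb, chosen after seeing the data, 3823 genes lost and 415 gained end regions and the flank difference was 0.61 points. Score thresholds reversed the body difference to 8.81 points (-log10 q of at least 5, 24 genes) and the flank difference to 16.5 points (4 genes) or 22.6 points (fold enrichment of at least 3, 2 genes).

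**Figure D3:**
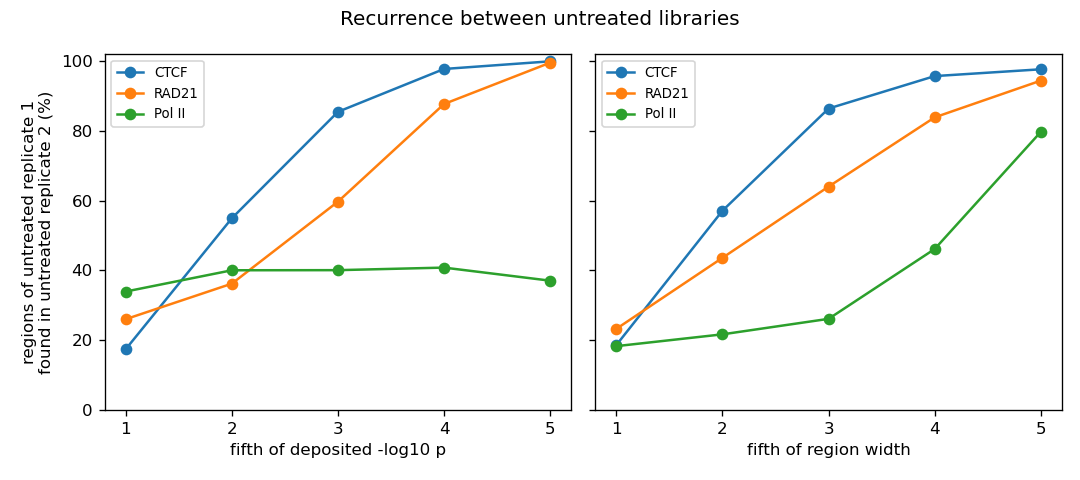
Share of regions of untreated replicate 1 found in untreated replicate 2, by quintile of the deposited -log10 p (left) and of region width (right), for CTCF, RAD21 and Pol II. For Pol II the share is 34.0, 40.05, 40.1, 40.8 and 37.1% by score and 18.3, 21.7, 26.1, 46.1 and 79.7% by width.

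**Figure D4:**
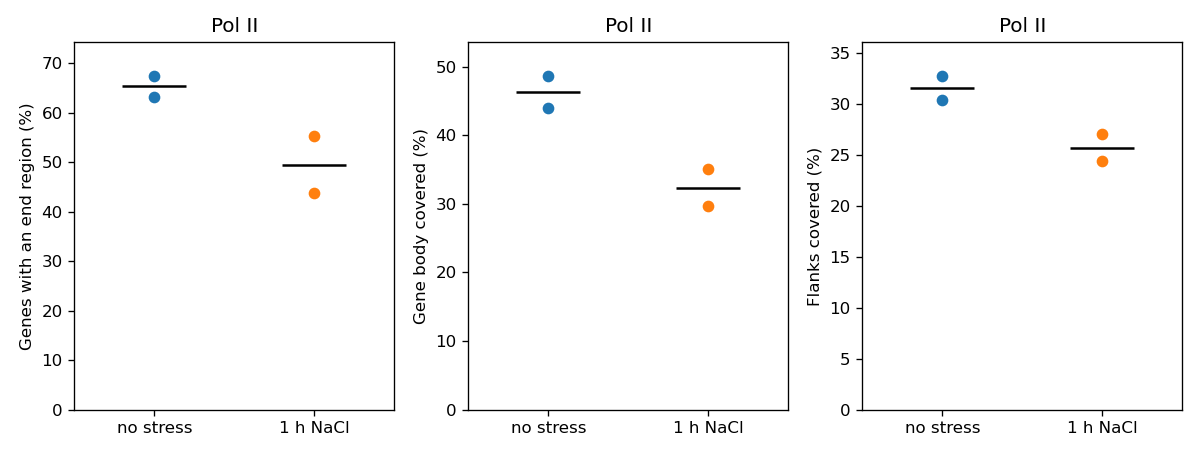
Percent of protein-coding genes with a Pol II region within 1 kb of an end (left), percent of the gene body covered (middle) and percent of both 10 kb flanks covered (right), with a point per library and a bar for the mean of 2. Both 1 h libraries lie below both untreated libraries in each panel, for example at 43.7 and 55.4% against 63.2 and 67.5% of genes.

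Gene groups were compared by their lost and gained Pol II end regions. The comparison was against the other genes with a region in any library, of which about 12.5% lost and 3.65% gained them. A gene could be lost only with a region in both untreated libraries and gained only with none there. Of 17113 genes 11054 had a region in both, as did 1 of 11 haematopoietic markers and 10 of 16 osmolyte pathway genes. The tests do not account for this difference. HOX clusters lost 6 of 19, at HOXD13, HOXA9, HOXC11, HOXC10, HOXC6 and HOXB4 (Fisher's exact p = 0.024, adjusted 0.456 over 19 lists), and haematopoietic markers gained 3 of 11, at LYZ, ITGAM and CD79A (p = 0.00642, adjusted 0.122). Transcription elongation and termination genes lost 5 of 19, at PCF11, CPSF3, CPSF4, CSTF2 and CSTF3, while CPSF1 and CSTF1 of the same list were not called (Fisher's exact p = 0.0783, adjusted 0.673). Glycolysis and housekeeping genes lost 4 of 17, at GAPDH, TUBB, B2M and PKM, ribosomal protein genes 4 of 32 with RPL27 gained, and protocadherins 5 of 24 with 2 gained. Immediate early genes lost 2 of 31, DUSP4 and MAFF, and gained 0, and heat shock genes lost HSPB1 and BAG3 of 17. In the osmolyte and NFAT5 pathway 0 of 16 were lost and SLC6A12, the betaine transporter, was gained. Luminal identity genes lost KRT8 and CDH1 and gained SPDEF and ESR1 of 18, although the covered share of ESR1, the oestrogen receptor gene, was 70.8 and 68.5% untreated and 31.1 and 31.2% at 1 h. Each of these groups had 2 lost members: the integrated stress response (VLDLR, CHAC1), histones (H1-4, H2BC5), cell cycle (CDC20, BUB1), neuronal and muscle markers (ACTA1, SNAP25) and imprinted genes (SNRPN, NNAT, with KCNQ1 gained). Loop factors lost PDS5A and gained CTCFL, fibroblast markers lost TWIST1, and oestrogen and progesterone targets lost 0 and gained 0 of 15. By Fisher's exact test with Benjamini-Hochberg adjustment 0 lists passed in either direction. HOX clusters passed for loss when all lists were set to an equal covered length by score, and haematopoietic markers passed for gain with equal numbers of regions by score.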

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

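The tests of depth, calling threshold, list length, sample tags and covered length below, the splits within pairs and the reading of the other splits were chosen after the results were seen, while the comparison over other splits was planned.

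Triptolide went with more peaks in some states and fewer in others, and these differences between groups rest on 1 library with triptolide per state, set against the library without of set 2, and were not tested. For RAD21 the log2 ratio with triptolide over without was 0.72 in unstressed cells and -0.99 at 1 h of NaCl, a difference of -1.70. In recovery it was 1.82, a difference of 2.81 from 1 h, but against each of the 3 recovery libraries without triptolide it ran from 0.17 to 2.38. For CTCF it was 0.11 in unstressed cells, -0.091 at 1 h and -0.43 in recovery, differences of -0.20 and -0.54 from unstressed cells. These follow the titles, and by the tags, which contradict the titles in 6 of 12 libraries, no such comparison exists within a state.

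RAD21 and CTCF had fewer peaks at 1 h of NaCl in every replicate. For RAD21 the caller's background gave no sign of a lower depth, as its lowest ratio at 1 h over untreated was 1.03. For CTCF depth stays open, with a lowest ratio of 0.946 (0.985 and 1.299 in the others). The control behind this background and its scaling are not given. The background need therefore not follow read totals, and it does not exclude a difference in depth for either protein. Weak CTCF sites falling under the calling threshold without a change of rank remain a candidate explanation, because with equal peak numbers 74.3% of untreated peaks were kept at 1 h (55.8 to 86.8%) and 74.9% between untreated libraries (63.9 to 86.0%). For RAD21 this stays open, with 62.9% kept (53.8 to 69.5%) against 72.4% between untreated libraries (64.5 to 77.8%), ranges that overlap. A change of binding under hyperosmotic stress, the treatment of the design, is also open, and a lower yield of the immunoprecipitation was not tested.

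The counts of lost and gained sites were set beside the 10 splits of the 6 libraries, too few for a share under 0.05. The larger of the lost and gained counts of each other split was used, since which of its groups comes first is arbitrary. For CTCF the real split lost 1498 sites, reached by 1 of 10 splits, with 1053 in the highest other. For RAD21 it lost 3271, reached by 1 of 10, with 413 in the highest other. The gained counts, 28 for CTCF and 2 for RAD21, were reached by 6 of 10 and 10 of 10. Here the smaller count of the real split was set against the larger count of the others. That comparison cannot decide whether the gained counts were unusual. In the 4 splits that keep libraries of a replicate in opposite groups, the highest other was 2 for CTCF and 187 for RAD21.

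RAD21 recovery libraries regained 81.4% of lost peaks in replicate 2 and 12.5 and 11.4% in replicates 1 and 3. The background of replicates 1 and 3 was at least 1.41 times that of replicate 2, which gives no sign of a lower depth. It does not exclude 1, since the background need not follow read totals. The shorter lists of replicates 1 and 3 remain a candidate explanation, since with equal peak numbers within a replicate 61.9, 60.8 and 59.4% were regained. Those shares cover only lost peaks among the strongest untreated ones, 1750 instead of 13716 in replicate 1 and 1974 instead of 18431 in replicate 3. They cannot tell whether weaker peaks returned. Triptolide in replicate 3, which its tag names, stays open, because the library with triptolide in both title and tag held 77.9% of untreated peaks and replicate 3 held 25.7%, but a single library excludes nothing. What made the lists differ in length, such as a difference between cultures in recovery, was not tested.

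Fewer genes had a Pol II region at an end at 1 h of NaCl. With lists reduced to equal covered length by width both 1 h libraries still had fewer such genes (8722 and 8920) than the untreated ones (9560 and 11209). The gap of 640 between the groups was smaller than the difference between the untreated libraries, so less called genome cannot be told apart from a change in Pol II. A fall in occupancy of gene ends under stress, the treatment of the design, stays open as well.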

How the results depend on the processing

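Regions of at least 2 kb and equal covered length by width were chosen after seeing the data, and the other alternatives were planned. Of 276 alternative values 215 stayed the same in direction and threshold or within the spread, 5 reversed, 3 lost a call and 53 moved. Some of the 215 could not change, because the library left out was not part of the comparison. Others counted as the same only through a large spread, such as the RAD21 regained share (SD 40.1). The tally is therefore no measure of how stable the results are. The fall of CTCF and RAD21 peak number at 1 h kept its direction in every alternative run. For CTCF with minimum fold enrichment the exact permutation p was 0.3 instead of 0.1, so untreated and 1 h libraries no longer separated completely. Where nothing else is said, the cause was not tested. Read depth is not in the lists and limits every count, and the CTCF motif comparison was not run.

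With -log10 q of at least 5, CTCF near gene ends against distal had a log2 odds ratio of 0.41 and lost its call, Pol II lost 1327 and gained 31 gene ends, and body and flank differences reversed to 8.81 and 16.5 points. The triptolide log2 ratios of CTCF were 0.16 unstressed and -0.060 at 1 h. With minimum fold enrichment, CTCF lost 754 and gained 8 sites, RAD21 gained 1, the gene-end log2 odds ratio was 0.35 without a call, Pol II lost 513 and gained 38 gene ends and its flank difference reversed to 22.6 points. Triptolide log2 ratios were then 0.31, -0.042 and -0.56 for CTCF and 0.51, -1.18 and 2.11 for RAD21 (unstressed, 1 h, recovery). These Pol II filters leave few genes and act on scores that hardly followed the width of their regions.

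With equal numbers of peaks, CTCF kept 74.3% with 693 lost and 175 gained sites, RAD21 kept 62.9% with 357 lost and 229 gained and regained 60.7% in recovery (SD 1.24), Pol II lost 4083 and gained 285 gene ends and 1 list passed for gain. With equal covered length 1 list passed for loss. Reciprocal overlap of 50% gave 62 gained RAD21 sites, and summits within 100 bp 43 gained CTCF and 7 gained RAD21 sites. In set 1 alone CTCF kept 63.3%, lost 9702 and gained 182 sites and RAD21 gained 26. Fewer libraries must share a site there, which bears on the counts and not on the kept share. How far this accounts for the counts was not tested. Within quintiles of fold enrichment the mean gene-end log2 odds ratio of CTCF was 1.23 without a call, since replicate 3 was near 0. A region over the gene end itself gave 409 gained Pol II genes. Regions of at least 2 kb gave 3823 lost and 415 gained genes and a flank difference reversed to 0.61 points, and equal covered length by width 994 gained.

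Leaving out single libraries gave 49.9 to 63.9% of CTCF peaks kept. It gave 1504 to 9689 CTCF sites lost and 33 to 155 gained, and 3352 to 7630 RAD21 sites lost and 2 to 17 gained. For Pol II it gave 2639 to 4981 genes lost and 985 to 1629 gained. Fewer libraries need to share a site in these counts. How much that matters depends on the library left out. Of the CTCF peaks of untreated replicate 2, 97.5% were overlapped by untreated replicate 1 and 59.2% by untreated replicate 3. Leaving out replicate 1 thus hardly loosened the requirement, with 1504 CTCF sites lost, and leaving out replicate 3 loosened it far more, with 9689 lost. The RAD21 log2 ratio of recovery over 1 h ran from -0.23, reversed without recovery replicate 2, to 0.87. The regained share ran from 11.985 to 47.0%, RAD21 peaks at CTCF from 2.79 to 11.3 points and CTCF peak number at 7.5 min from -0.82 to -0.37.

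With the replicate block, pairs of the same number or set kept 59.6% of CTCF and 33.1% of RAD21 peaks, and the sign-flip p of peak number was 0.25 for both (exact, the smallest with 3 pairs). The block changed no call, and for Pol II its counts equal the unpaired ones by construction. RAD21 and Pol II numbers did not pair the libraries (r = -0.045, 0.20 and 0.089 for RAD21 and -0.0035 for Pol II), and not every CTCF library correlated best with its own number.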

Other observations

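The tests in this part were all chosen after the results were seen.

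Pol II coverage rose in genes beside HSP90AB1 and in a pair of adjacent genes on chromosome 19. HSP90AB1, a cytosolic HSP90 chaperone gene (chromosome 6, 44246194 to 44253883), was fully covered in all 4 libraries. Beside it, NFKBIE (44258166 to 44265551) was covered over 1.83 and 1.79% untreated and 100.0% in both 1 h libraries, and TMEM151B (44270450 to 44279444) over 14.6 and 0.0% untreated and 87.6 and 33.8% at 1 h. ZFR2 (chromosome 19, 3804024 to 3869038) went from at most 4.21% to 75.0 and 73.7%, and the adjacent ATCAY from at most 1.81% to 100.0%. These neighbourhoods were noticed among the genes named by the rule and were not tested. Among single genes of the lists, EGR1 went from 30.3 and 23.6% to 100.0% in both 1 h libraries, FOSB from 33.7 and 34.1% to 100.0% and AQP3, a water and glycerol channel, from 9.0 and 11.8% to 100.0 and 53.6%. NFAT5, the osmotic stress transcription factor, fell from 87.2 and 77.1% to 29.9 and 19.1% and the kinase gene WNK1 from 57.8 and 50.4% to 3.8 and 5.19%. These single genes were picked after their values were seen and were not tested either.

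Pol II past gene ends was followed by orienting genes through their CTCF or RAD21 peaks, since the gene table has no strand. A gene with an untreated peak at a single end was read as starting there, which placed 28 of 29 genes of known strand correctly (96.6%, exact 95% interval 82.2 to 99.9%). The hypothesis that Pol II covers more of the far flank at 1 h was not borne out with every region counted. The far flank of 597 genes was covered over 40.8 and 37.5% untreated and 30.4 and 27.2% at 1 h, the lowest 1 h minus the highest untreated value being -13.6 points, and the near flank of 628 genes over 23.8 and 22.3% untreated and 30.2 and 26.0% at 1 h. With regions of at least 2 kb the far flank of 229 genes was covered over 49.9 and 46.7% untreated and 48.2 and 39.8% at 1 h, and the score thresholds left at most 4 genes.

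RAD21 peaks at CTCF were kept more often than others within quintiles of fold enrichment too, with log2 odds ratios of 1.43, 0.66 and 3.69 in replicates 1 to 3.

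Among Pol II regions of equal width, recurrence in the replicate rose from the lowest to the highest quintile of score by 3.79 points on average and 11.8 at most, against averages of 38.7 for CTCF and 40.4 for RAD21 with lowest values of 2.68 and 9.42. Averaging of the score over each region stays open as an explanation, since the highest Pol II rise lay above the lowest CTCF and RAD21 rises. With the Pol II scores moved by any of up to 3000 lines in either direction, the correlation of score and width was at most 0.023. Why the scores hardly followed width remains unknown, and the values do not show that they are wrong.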
